A study of Homo sapiens with 18 samples.

How the data were processed

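RNA from 18 samples, 8 of HCT116 cells and 10 of human lung fibroblasts, had been measured on 1-colour Illumina bead arrays. Per the labels, RNA was extracted with Trizol and a column kit with DNase treatment and amplified as labelled cRNA with an Ambion MessageAmp kit. The build of the array platform was not named. The values used are the deposited linear intensity of each probe, which the authors had normalized by a method the labels do not state. The upper quartiles lay between 61.0 and 66.8 on all arrays, the highest 1% of probes began between 5264 and 11574, and small negative values were present on some arrays. A second table of non-normalized signals with detection p-values holds 36 columns whose names match no sample label, so it was not used here. The plan, fixed before the data were examined, was to background-correct with detection p-values from that table, and this was replaced by a correction that needs none.

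Intensities were background-corrected with the normexp method (offset 16), log2-transformed and quantile-normalized within each cell system with limma 3.58.1 in R 4.3.3, and over all 18 arrays for the comparison of cell systems. A probe was above background on an array when its deposited intensity exceeded the array's mode by 1.645 SD, with the SD taken from the values below the mode. Probes above background on at least 2 arrays were kept. Probes were named through Entrez identifiers, with 28087 probes carrying 1 gene symbol, 13 several and 20689 none, and 28048 matched to the gene table. Each gene was represented by its brightest passing probe, and Y-linked genes, XIST and TSIX were left out. Array signal relative to background limits what can be seen of dim genes, and in a comparison of 2 groups a gene at background in 1 of them is given as at least a fold. In a difference of responses no such bound was computed, and the values of genes at background in some group depend on the offset.

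Groups were the cell system, genotype or siRNA, and treatment given by the labels, with replicate numbers not treated as pairs, because same-number arrays were correlated between -0.11 and 0.22 after group means were removed. Linear models with empirical Bayes variances were fitted for each comparison, with 4, 6 and 10 residual degrees of freedom in HCT116, fibroblasts and all arrays. The comparisons were the 4 doxorubicin responses, the genotype and siRNA differences in response (interaction terms), the genotype and siRNA differences within each treatment, and the difference between the p53+/+ HCT116 and control siRNA fibroblast responses. All tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Where an array left out leaves a group with 1 array, that array is assumed to vary like the other groups.

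The 19 gene lists, written before the data were examined, were p53 targets, p53 apoptosis targets, p53 DNA repair targets, G2/M and mitosis, G1/S and DNA replication, homologous recombination and Fanconi anemia, histone genes, NF-kB and inflammatory secretion, interferon-stimulated genes, unfolded protein and ATF4 response, cholesterol synthesis, immediate-early genes, ribosome biogenesis, heat shock proteins, fibroblast and matrix markers, epithelial markers, endothelial markers, blood cell markers and CDKN1A neighbours. Lists were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 19 lists of a comparison. Genes were named by a rule set at the same time: CDKN1A and MDM2 always, the 6 largest called increases and decreases among genes with a proper symbol above background on every array of a compared group, and up to 4 measured members of each list described, which may also be given in matching comparisons of the same cell system. Where at most 5 genes were called all were to be named. The p53-dependent set holds genes called in the p53+/+ response and called in the same direction in the genotype difference in response. Overlaps were tested with Fisher's exact test, and the share of the response remaining under the DINO siRNA is a slope through the origin across genes.

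The alternatives tried were an offset of 50, no background correction, median scaling, the deposited values without further normalization, no filter and a stricter filter on dim probes, the mean of all probes of a gene, an intensity trend with a robust prior, array weights, replicate number as a block, all 18 arrays together, only the arrays compared, at least a 2-fold change, fry, an estimated correlation, and each array left out in turn. A fit without the DINO siRNA untreated arrays was added after the data were seen. The methods were tested on simulated data in which 100 genes each were given a 2-fold and a 4-fold change. Of the 2-fold changes 31% to 98% were called, with 58% and 51% in the genotype and siRNA differences in response, and of the 4-fold changes 99% to 100%, with 6 to 19 unchanged genes called per comparison.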

Results

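Gene expression was measured with 1-colour Illumina bead arrays in a pair of human cell systems after DNA damage by doxorubicin, an anthracycline that traps topoisomerase II on DNA. The first system was HCT116, a colon cancer cell line, as p53+/+ cells and as p53-/- cells that lack the tumour suppressor and transcription factor p53. The second was human lung fibroblasts transfected with a control siRNA or with an siRNA against DINO, a damage-induced long noncoding RNA transcribed next to CDKN1A. Cells received 200 ng/mL doxorubicin or a sham treatment for 26 hours. Each HCT116 group and each control siRNA group had 2 arrays and each DINO siRNA group had 3, which makes 18 arrays in 8 groups. On each array, 42.2% to 49.9% of the probes were above that array's background. Across genes, replicate arrays correlated with r between 0.987 and 0.996. After dim probes were removed, 14488 genes were tested in HCT116, 14814 in the fibroblasts and 16223 where the systems were compared. The small number of arrays limits the precision, and the p-values measure only the spread between these arrays, since the labels call them biological replicates without saying how the cultures were kept. Fold changes below are log2 values with their standard error from limma, and p-values are adjusted by the Benjamini-Hochberg method. The level of DINO is not analysed here, so the knockdown was not checked on its target.

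The response of p53+/+ HCT116 cells asks which genes follow DNA damage where p53 is present. TP53I3, a p53 target that encodes a quinone oxidoreductase-like enzyme, rose 43.2-fold (log2 5.43 ± 0.17, n = 2 and 2, limma adjusted p = 2.5e-11) on its brightest probe and by a log2 value of 2.20 on a second probe. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose 7.45-fold (log2 2.90 ± 0.17), and MDM2, the ubiquitin ligase that degrades p53, rose 4.13-fold (log2 2.05 ± 0.17). A second, dimmer MDM2 probe gave -0.18. In the list of p53 targets, 59 of 68 measured genes rose (59 adjusted over the list alone), with a median log2 change of 1.36. In the list of genes for G2/M and mitosis, 52 of 53 fell (53 adjusted over the list alone), with a median of -1.55.

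Other large increases were in CBS, the cystathionine beta-synthase of transsulfuration (4.98 ± 0.17), the aldo-keto reductase AKR1B10 (4.55 ± 0.22) and CYSRT1 (3.51 ± 0.19). AKR1B15 and the sortilin-family receptor SORCS2 were not above background in untreated cells and rose at least 9.38-fold and at least 9.87-fold. Among p53 targets, KLHL30 (3.48 ± 0.18) and the stress-induced TP53INP1 (3.37 ± 0.17) followed TP53I3. Of the p53 targets linked to apoptosis, 13 of 18 rose (13 adjusted over the list alone), including APAF1, the core of the apoptosome (2.02 ± 0.17), and the death-domain protein PIDD1 (1.79 ± 0.16). Of those linked to DNA repair, 5 rose and 1 fell among 7 measured (6 and 1 adjusted over the list alone), with RRM2B, a ribonucleotide reductase subunit, at 2.11, the damage sensors XPC and DDB2 at 1.40 and 1.04, and GADD45A at 1.61. The mitotic genes with the largest decreases were HMMR (-2.97 ± 0.24), the spindle checkpoint kinases BUB1 (-2.73 ± 0.17) and TTK (-2.60 ± 0.24), and BORA, an activator of Aurora A (-2.57 ± 0.18). DEPDC1 (-2.91), FAM72D (-2.70) and PCK2, the mitochondrial phosphoenolpyruvate carboxykinase (-2.92), also fell. The genes of this paragraph had adjusted p-values from 5.4e-11 to 4.8e-04.

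For G1/S and DNA replication, 2 rose and 24 fell among 44 measured (3 and 27 adjusted over the list alone), with the primase subunit PRIM1 at -1.63 and the polymerase subunit POLE2 at -1.57. In homologous recombination and Fanconi anemia, 12 of 21 fell (13 adjusted over the list alone), among them the checkpoint kinase CHEK1 (-1.55) and BRCA1 (-1.28). By camera, the p53 targets (adjusted p = 3.3e-38), apoptosis targets (1.9e-10), G2/M genes (1.0e-43) and recombination genes (1.8e-05) were called, and these calls held with an estimated correlation (adjusted p = 0.014, 0.016, 0.016 and 0.035). The calls for the repair targets (camera adjusted p = 2.3e-04) and for G1/S genes (1.0e-09) were lost with it (adjusted p = 0.082 and 0.12 with an estimated correlation). For histone genes, 9 rose and 4 fell among 21 measured (9 and 5 adjusted over the list alone), with H2BC5 at 2.92 (camera adjusted p = 0.023, adjusted p = 0.41 with an estimated correlation). Interferon-stimulated genes gave 9 of 35 higher (10 adjusted over the list alone), among them ISG15 (2.10) and the peptide transporter TAP1 (2.02), with camera adjusted p = 0.0068 and adjusted p = 0.082 with an estimated correlation. In the unfolded protein and ATF4 list, 3 rose and 12 fell among 29 measured (3 and 12 adjusted over the list alone), with asparagine synthetase ASNS at -2.50 and the cystine transporter SLC7A11 at -1.86 (camera adjusted p = 0.0030, adjusted p = 0.26 with an estimated correlation). Fibroblast and matrix markers included ACTA2, smooth muscle actin (3.06), and the matricellular protein CCN2 (2.48), and 6 rose and 1 fell among 26 measured (6 and 1 adjusted over the list alone) (camera adjusted p = 0.023, adjusted p = 0.12 with an estimated correlation).

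Over all 14488 genes, 1736 were higher and 1488 lower in doxorubicin-treated p53+/+ cells. With median scaling in place of quantile normalization the split was 1231 higher and 2584 lower. Leaving out untreated replicate 1 gave 938 and 701, untreated replicate 2 gave 1060 and 785, and doxorubicin replicate 1 gave 1128 and 912.

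**Figure D1:**
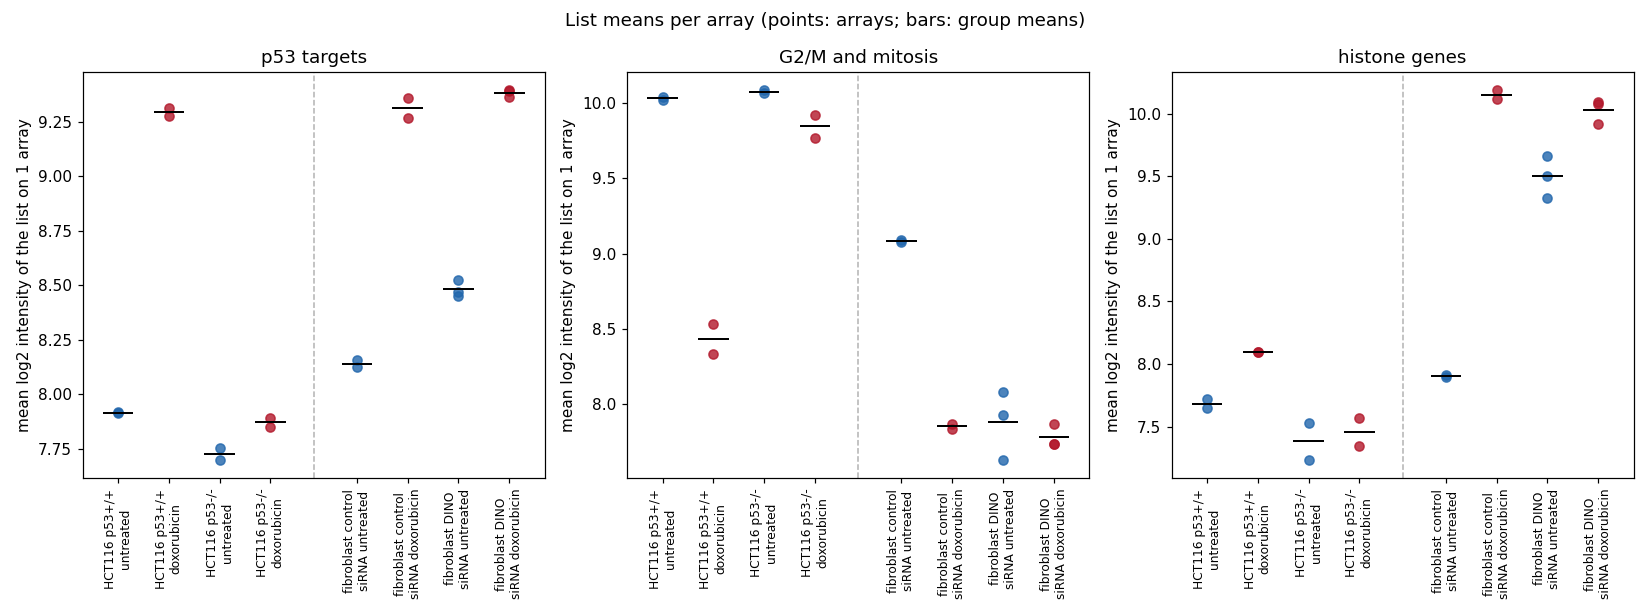
Mean log2 intensity of the members of 3 gene lists on each array (points), by group, with group means (bars); red points are doxorubicin arrays and blue points untreated arrays, and each cell system was normalized on its own. The p53 targets averaged 7.92 and 9.30 in untreated and treated p53+/+ HCT116 cells, and 7.73 and 7.87 in p53-/- cells.

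The same treatment of p53-/- HCT116 cells asks what doxorubicin changes without p53. ANKRD37 rose 16.2-fold (log2 4.02 ± 0.18, n = 2 and 2, limma adjusted p = 2.9e-09) and the secreted lipase inhibitor ANGPTL4 rose 15.3-fold (log2 3.94 ± 0.17). The glucose transporter SLC2A3 (3.41 ± 0.16), the transcriptional repressor BHLHE40 (3.39 ± 0.17), the keratin KRT80 (3.44 ± 0.18) and the chloride channel protein CLIC3 (3.33 ± 0.18) also rose. In the list of p53 targets, 14 rose and 5 fell among 68 measured (15 and 5 adjusted over the list alone), with a median of 0.07 (camera adjusted p = 0.14). MDM2 was at -0.08 ± 0.17 (adjusted p = 0.80), while CDKN1A still rose 4.51-fold (log2 2.17 ± 0.17, adjusted p = 1.2e-06) on its brightest probe and was at -0.07 on a second, dimmer probe.

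Other p53 targets that rose were SERTAD1 (1.55 ± 0.17), PMAIP1, the BH3-only protein NOXA (1.34 ± 0.19), GADD45A (1.31 ± 0.18) and TP53I3 (1.20 ± 0.17), which was at -0.30 on a second probe and lost its call with the mean of all its probes (0.45, adjusted p = 0.070). KITLG, the KIT ligand, fell (-1.96 ± 0.20). For immediate-early genes, 14 rose and 2 fell among 27 measured (16 and 2 adjusted over the list alone), and JUN (2.58 ± 0.17), ATF3 (2.36 ± 0.17), FOSB (2.00 ± 0.16) and FOS (1.87 ± 0.16), all subunits or partners of stress-activated AP-1 factors, were among those that rose. In the list for NF-kB and inflammatory secretion, 11 of 24 rose (11 adjusted over the list alone), including the chemokine CXCL8 (2.61 ± 0.18) and the inhibitor NFKBIA (1.25 ± 0.16). For heat shock proteins, 1 rose and 8 fell among 17 measured (1 and 11 adjusted over the list alone), with HSPA6 at -2.68 ± 0.17, HSPA1B at -1.93 ± 0.17 and the co-chaperone DNAJB1 at -1.21 ± 0.18. For interferon-stimulated genes, 13 rose and 3 fell among 35 measured (13 and 3 adjusted over the list alone), with IFI6 at 2.30 and the exonuclease ISG20 at 1.76. For G2/M genes, 3 rose and 14 fell among 53 measured (4 and 14 adjusted over the list alone), including cyclin B1 (CCNB1, -1.17) and HMMR (-1.20). CCN2 (2.71) and the actin-binding TAGLN (2.32) rose, and the neurotensin receptor NTSR1 (-2.97), PWWP3A (-2.35), TIGD5 (-2.35), RBM12 (-2.01) and epsilon-tubulin TUBE1 (-1.99) fell.

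The camera calls in p53-/- cells for immediate-early genes (adjusted p = 3.9e-07), NF-kB genes (4.3e-05), heat shock proteins (1.7e-04), interferon-stimulated genes (0.0011) and G2/M genes (0.0063) were each lost with an estimated correlation (adjusted p = 0.21, 0.21, 0.21, 0.21 and 0.40 with an estimated correlation). For epithelial markers, 7 rose and 1 fell among 24 measured (8 and 1 adjusted over the list alone) (camera adjusted p = 0.019, adjusted p = 0.28 with an estimated correlation), and blood cell markers gave 3 of 11 higher (3 adjusted over the list alone, camera adjusted p = 0.040, adjusted p = 0.40 with an estimated correlation). Over all genes, 1591 were higher and 1678 lower. Leaving out doxorubicin replicate 1 gave 741 and 789, and doxorubicin replicate 2 gave 891 and 995, and the G2/M call and that of HMMR were lost without replicate 1.

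The difference between these responses tests whether the response differs by genotype, as the p53+/+ response minus the p53-/- response. Other differences between these cells cannot be told apart from p53. Untreated, 1289 genes were already higher and 1136 lower in p53+/+ cells. CBS differed by a log2 value of 4.93 ± 0.24 (n = 2 in each of 4 groups, limma adjusted p = 2.2e-08), AKR1B10 by 4.33 ± 0.31, TP53I3 by 4.23 ± 0.24, TP53INP1 by 3.87 ± 0.25 and MDM2 by 2.12 ± 0.25. Second probes gave 2.50 for TP53I3 and -0.48 for MDM2. CDKN1A differed by 0.72 ± 0.25 on its brightest probe and did not pass (adjusted p = 0.063). On its second probe CDKN1A changed by 1.496 in p53+/+ cells and differed by 1.56 between genotypes, and with the mean of both probes it passed (1.14, limma adjusted p = 0.0030). Of the p53 targets, 45 of 68 measured genes were higher in this difference (50 adjusted over the list alone), with a median of 1.12. Of the G2/M genes, 49 of 53 were lower (52 adjusted over the list alone), with a median of -1.33.

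Further genes higher in this difference were SORCS2 (3.83), AKR1B15 (3.72), KLHL30 (3.13), pantothenate kinase PANK1 (2.91), RRM2B (2.18), PIDD1 (1.83), APAF1 (1.44), XPC (1.34) and ACTA2 (2.39). CBS, AKR1B15, SORCS2, KLHL30 and LBH were at background in at least 1 of the 4 groups, so their values in this difference depend on the offset and are no bounds. Apoptosis targets gave 9 of 18 (11 adjusted over the list alone) and repair targets 3 of 7 (3 adjusted over the list alone) higher. Mitotic genes lower in it included TTK (-2.50), the kinetochore proteins CENPE (-2.38) and NUF2 (-2.14), and DLGAP5 (-2.11). In homologous recombination and Fanconi anemia, 11 of 21 were lower in this difference (12 adjusted over the list alone), with BRCA1 at -2.15 and the ubiquitin-conjugating UBE2T at -2.05, and for G1/S 14 of 44 were (22 adjusted over the list alone), with POLE2 at -1.72. The lowest values in it were those of ANKRD37 (-3.99), SLC2A3 (-3.53), ANGPTL4 (-3.44), MIX23 (-3.32), LBH (-2.88) and uridine phosphorylase UPP1 (-2.74). For immediate-early genes, 1 was higher and 11 lower among 27 measured (1 and 14 adjusted over the list alone), with JUN at -2.60, EGR1 at -2.54 and FOS at -2.51. Adjusted p-values of the genes named for this difference, other than CDKN1A, ran from 2.2e-08 to 0.0020.

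By camera, the p53 targets (adjusted p = 3.9e-28), apoptosis targets (8.5e-08), G2/M genes (3.2e-33) and recombination genes (2.4e-07) differed, and all 4 calls held with an estimated correlation (adjusted p = 0.020 each). The calls for G1/S genes (camera adjusted p = 3.7e-08), immediate-early genes (4.1e-06) and repair targets (0.011) were lost (adjusted p = 0.17 each with an estimated correlation). Over all genes, 1115 were higher and 936 lower in this difference, and with median scaling 867 and 1432. The counts moved from 580 and 423 without p53+/+ untreated replicate 1 to 1679 and 1601 without p53-/- untreated replicate 2. They also fell by more than 1.5 times without p53+/+ untreated replicate 2 (620 and 468), p53+/+ doxorubicin replicate 1 (676 and 540) or 2 (609 lower), and p53-/- doxorubicin replicate 1 (645 and 479) or 2 (634 and 446).

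The genotypes were also compared within each treatment. In untreated cells, CDKN1A was 4.98-fold higher in p53+/+ than in p53-/- cells (log2 2.32 ± 0.17, n = 2 and 2, limma adjusted p = 6.9e-07), and the stress cytokine GDF15 was 4.90-fold higher (log2 2.29 ± 0.16). In doxorubicin the differences were 3.04 ± 0.17 and 3.13 ± 0.16, and MDM2 went from -0.14 ± 0.17 (adjusted p = 0.63) untreated to 1.98 ± 0.17, while its second probe went from 0.37 to -0.11. Interferon-stimulated genes were higher in untreated p53+/+ cells, where 20 were higher and 1 lower among 35 measured (21 and 2 adjusted over the list alone). Of these genes, IFI35 was at 2.10, IFI6 at 1.86 and the transcription factor IRF9 at 1.64 (camera adjusted p = 2.0e-09, and adjusted p = 0.032 with an estimated correlation). The regulator RGS2 (4.67), the calcium-binding S100A4 (3.46) and the translation factor EIF4E3 (3.10) were higher in untreated p53+/+ cells, and PROM1, CASP4 and EHF, at background in p53-/- cells, were at least 15.2-fold, 11.2-fold and 5.79-fold higher. Lower in untreated p53+/+ cells were ZBED2 (-4.91), TMEM200A (-2.82), the metalloprotease ADAM19 (-2.74), TM4SF18 (-2.64), DNER (-2.46), the kinase PLK2 (-1.69), E2F7 (-1.15), ribonucleotide reductase RRM2 (-1.54), HSPA6 (-2.03) and HSPA1B (-1.03). WNT16 was at -2.64 on its brightest HCT116 probe and at 0.16 on the probe that is brightest over all 18 arrays. Adjusted p-values of the genes called in untreated cells ran from 8.7e-11 to 0.0012.

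With doxorubicin, TP53I3 (5.04 ± 0.17), TP53INP1 (4.82 ± 0.17), AKR1B10 (4.57 ± 0.22), PROM2 (4.30 ± 0.16) and ACTA2 (4.20 ± 0.16) were higher in p53+/+ cells, as were KLHL30 (3.21), RRM2B (2.53) and XPC (1.96), and CBS was at least 36.7-fold higher. SLC2A3 (-4.79 ± 0.16), ANKRD37 (-3.08 ± 0.18), ANGPTL4 (-3.03 ± 0.17), LBH (-2.94) and UPP1 (-2.77) were lower, and STXBP6 was at least 5.66-fold lower (adjusted p from 3.2e-11 to 7.3e-07 for the genes named in doxorubicin). In doxorubicin, 52 of 68 p53 targets were higher in p53+/+ cells (54 adjusted over the list alone) and 51 of 53 G2/M genes were lower (52 adjusted over the list alone), against 16 of 68 and 8 of 53 in untreated cells (18 adjusted over the list alone, and 8). The camera calls in doxorubicin for p53 targets (adjusted p = 9.1e-30) and G2/M genes (1.9e-34) held with an estimated correlation (adjusted p = 0.019 each), and neither list was called in untreated cells (camera adjusted p = 0.071 and 0.40). In all, 1289 genes were higher and 1136 lower in untreated p53+/+ cells, and 2067 and 1778 in doxorubicin. For untreated cells median scaling gave 1898 and 718, and a fit of only the 4 arrays compared, with the normalization unchanged, gave 811 and 683. Leaving out 1 array gave from 443 and 305 without p53+/+ replicate 2 (486 and 333 without replicate 1) to 1797 and 1745 without p53-/- replicate 2. Those p53-/- replicates lay apart on the third principal component (-30.0 and -5.08). Without p53-/- replicate 1 the untreated counts were 706 and 478. In doxorubicin the lower genes numbered 1131 without p53+/+ replicate 1, 1172 without p53-/- replicate 1 and 1039 without p53-/- replicate 2.

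**Figure D2:**
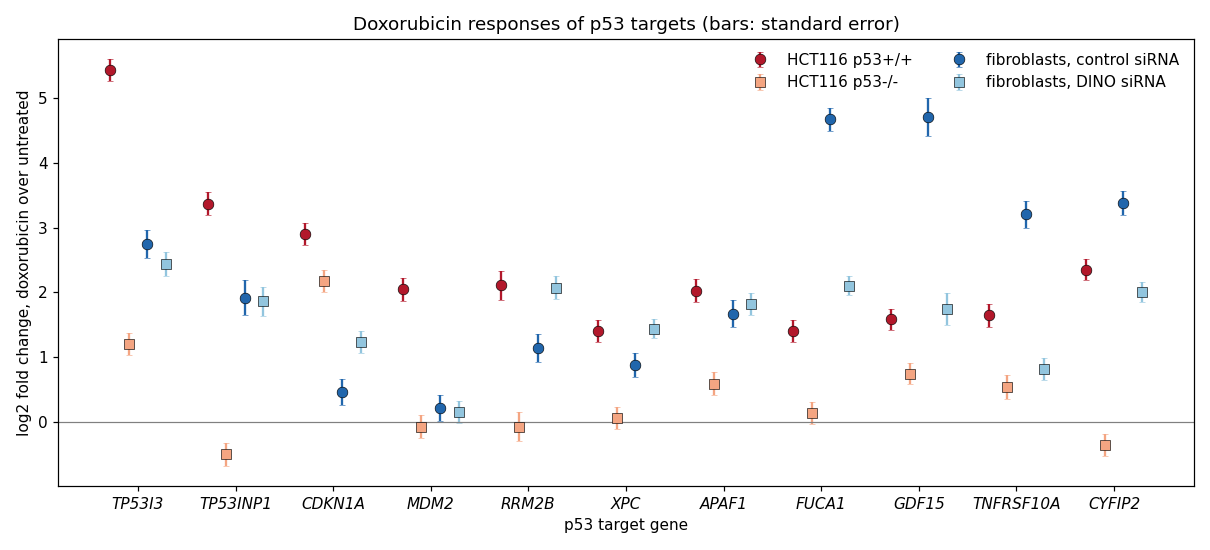
Log2 fold changes (doxorubicin over untreated, bars are standard errors) of 11 p53 target genes in the 4 doxorubicin responses. TP53I3 changed by 5.43 in p53+/+ and 1.20 in p53-/- HCT116 cells, and by 2.74 and 2.44 in fibroblasts with control and DINO siRNA.

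In fibroblasts with the control siRNA, p53 targets and histone genes rose with doxorubicin and mitotic genes fell. FUCA1, a lysosomal fucosidase and p53 target, rose 25.5-fold (log2 4.67 ± 0.18, n = 2 and 2, limma adjusted p = 5.0e-12), GDF15 rose 26.2-fold (log2 4.71 ± 0.30) and TP53I3 rose 6.69-fold (log2 2.74 ± 0.22). CDKN1A was at 0.46 ± 0.20 (adjusted p = 0.082) and MDM2 at 0.21 ± 0.20 (adjusted p = 0.45). Of the p53 targets, 50 rose and 3 fell among 70 measured (52 and 3 adjusted over the list alone), with a median of 1.07. For histone genes, 20 rose and 1 fell among 23 measured (20 and 1 adjusted over the list alone), with a median of 2.12 (adjusted p = 0.068 with an estimated correlation). For G2/M genes, 3 rose and 38 fell among 53 measured (4 and 40 adjusted over the list alone), with a median of -1.47 (adjusted p = 0.17 with an estimated correlation).

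Large increases were in the stress transcription factor ATF3 (5.19 ± 0.18), the growth factor receptor FGFR3 (5.04 ± 0.19), and the small nucleolar RNA SNORD13 (4.89 ± 0.36). GRAP, CRTAC1 and the transcription factor HAND1 were at background in untreated cells and rose at least 37.1-fold, 27.2-fold and 20.4-fold. CYFIP2 (3.38 ± 0.19), the death receptors TNFRSF10A (3.20 ± 0.20) and TNFRSF10B (2.33 ± 0.19), PMAIP1 (1.96), GADD45A (1.64) and DDB2 (1.56) rose among p53 targets. Apoptosis targets gave 10 of 18 higher (11 adjusted over the list alone), and repair targets 6 of 7 (6 adjusted over the list alone). The histone genes H2AC18 (4.73 ± 0.20), H2AC20 (4.45 ± 0.22) and H2BC8 (3.72 ± 0.20) rose, with the limit that probes for histones and small RNAs can share sequence with near-identical copies. Mitotic genes that fell were DLGAP5 (-3.22 ± 0.18), CCNB1 (-3.09 ± 0.20), ECT2, a regulator of cytokinesis (-2.93 ± 0.20), and the kinesin KIF11 (-2.88 ± 0.23). For cholesterol synthesis, 1 rose and 12 fell among 20 measured (1 and 14 adjusted over the list alone), with squalene epoxidase SQLE at -3.25 and HMGCS1 at -2.18. For fibroblast and matrix markers, 1 rose and 15 fell among 33 measured (1 and 15 adjusted over the list alone), with the receptor PDGFRA at -2.64, CCN1 at -2.16 and collagen COL1A1 at -1.85. For ribosome biogenesis, 3 rose and 14 fell among 34 measured (3 and 14 adjusted over the list alone), with the acetyltransferase NAT10 at -1.98 and dyskerin DKC1 at -1.61. TNFRSF19 (-4.52), the regulator RGS4 (-3.65), the splicing factor SRSF3 (-3.65), the oxytocin receptor OXTR (-3.47) and NREP (-3.46) fell. The hyaluronan synthase HAS2 was at -4.00 on its main probe but near 0.20 to 0.23 on the probe that is brightest under 3 other settings.

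By camera the p53 targets were called (adjusted p = 3.3e-14, and adjusted p = 0.0060 with an estimated correlation). The calls for histones (adjusted p = 3.3e-14), G2/M genes (4.8e-14), apoptosis targets (2.1e-05), repair targets (0.0010), cholesterol synthesis (6.8e-05), matrix markers (0.0062) and ribosome biogenesis (0.0022) were lost (adjusted p = 0.068, 0.17, 0.068, 0.084, 0.084, 0.32 and 0.32 with an estimated correlation). Over all 14814 genes, 2957 were higher and 2982 lower, and the genes named as changed had adjusted p-values from 4.6e-12 to 2.6e-04. CDKN1A passed the threshold in this response under 5 other settings, with values from 0.42 to 0.75.

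In fibroblasts with the DINO siRNA, doxorubicin also raised p53 targets, while G2/M genes went both ways. TP53I3 rose 5.41-fold (log2 2.44 ± 0.18, n = 3 and 3, limma adjusted p = 2.8e-08), FUCA1 rose 4.29-fold (log2 2.10 ± 0.15) and RRM2B rose 4.20-fold (log2 2.07 ± 0.18). CDKN1A rose 2.35-fold (log2 1.24 ± 0.17, adjusted p = 1.0e-05) on its brightest probe and was at -0.49 on a second probe, and MDM2 was at 0.15 ± 0.17 (adjusted p = 0.51). Of the p53 targets, 55 rose and 3 fell among 70 measured (56 and 4 adjusted over the list alone), with a median of 0.91 (camera adjusted p = 3.6e-14, and adjusted p = 0.0057 with an estimated correlation). For G2/M genes, 12 rose and 19 fell among 53 measured (14 and 19 adjusted over the list alone), with a median of -0.01 (camera adjusted p = 0.39). This response is measured against the DINO siRNA untreated arrays, which stood apart from the other fibroblast arrays on the second principal component (-51.7 to -41.7, against 14.6 to 24.4). The G2/M genes averaged a log2 intensity of 7.88 on those arrays and 7.78 with doxorubicin, against 9.08 and 7.85 with the control siRNA.

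For apoptosis targets, 13 rose and 1 fell among 18 measured (13 and 1 adjusted over the list alone), with TP53INP1 at 1.86, APAF1 at 1.81 and PIDD1 at 1.65. Of the repair targets, 7 of 7 rose (7 adjusted over the list alone), with XPC and GADD45A at 1.44 and 1.44. These camera calls (adjusted p = 8.6e-05 and 5.8e-05) were lost with an estimated correlation (adjusted p = 0.086 and 0.076). CYFIP2 rose by a log2 value of 2.01 ± 0.15. The largest increases were in CCDC3 (2.87 ± 0.15), the cardiac-type repressor ANKRD1 (2.86 ± 0.17), the glycolytic regulator PFKFB4 (2.79 ± 0.19), CRIP1 (2.75 ± 0.15), the actin-bundling ESPN (2.69 ± 0.17) and the intermediate filament SYNM (2.67 ± 0.17). The largest decreases were in the homeobox gene HOXD1 (-3.43 ± 0.17), the chemokine receptor CXCR4 (-3.29 ± 0.21), osteoprotegerin TNFRSF11B (-3.20 ± 0.17), the retinoic acid hydroxylase CYP26B1 (-3.09 ± 0.17) and EPB41L4A-DT (-3.04 ± 0.19). SOX2, at background in doxorubicin, fell at least 5.85-fold. Of the G2/M genes, BORA (-1.62), the kinase PBK (-1.56) and the cytokinesis protein ANLN (-1.49) fell and Aurora B (AURKB, 1.24) rose. Histones gave 13 of 23 higher (13 adjusted over the list alone), with H4C14 at 1.88 (camera adjusted p = 0.0039, adjusted p = 0.46 with an estimated correlation). For cholesterol synthesis, 1 rose and 10 fell among 20 measured (1 and 10 adjusted over the list alone), with lanosterol synthase LSS at -2.68 (camera adjusted p = 4.9e-04, adjusted p = 0.15 with an estimated correlation). FOSB (-2.78), CXCL8 (-2.36), the adhesion molecule VCAM1 (-2.30) and cyclooxygenase PTGS2 (-1.98) fell, of which FOSB, CXCL8 and VCAM1 were higher in the DINO siRNA than in the control siRNA untreated arrays. In the NF-kB list, 10 rose and 9 fell among 32 measured (11 and 9 adjusted over the list alone), with a median of 0.03, a mean of -0.10 and a camera direction of down (adjusted p = 0.84). Over all genes, 3484 were higher and 2872 lower, and the genes named as changed had adjusted p-values from 1.3e-09 to 9.5e-05.

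Whether the DINO siRNA changed the response was tested as the DINO siRNA response minus the control siRNA response. FUCA1 (-2.57 ± 0.24, n = 2 or 3 per group, limma adjusted p = 3.8e-07), GDF15 (-2.97 ± 0.38), TNFRSF10A (-2.39 ± 0.26) and ANKRA2 (-1.70 ± 0.28) were lower in this difference. The mitotic genes KIF11 (3.83 ± 0.29), CCNB1 (3.53 ± 0.26), ECT2 (3.21 ± 0.26) and CENPE (3.20 ± 0.24) were higher in it. For the p53 targets, 9 were higher and 16 lower among 70 measured (10 and 16 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 0.12). CDKN1A was at 0.78 ± 0.26 (adjusted p = 0.029), with -0.87 on its second probe and a call that ended with the mean of its probes (-0.05), and MDM2 was at -0.06 ± 0.26 (adjusted p = 0.89). Between the siRNAs themselves, 3380 genes were higher and 3391 lower with the DINO siRNA in untreated cells, against 2 and 11 in doxorubicin.

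In untreated cells the DINO siRNA arrays had higher levels of FOSB (6.33 ± 0.16), the small nuclear RNA RN7SK (5.29 ± 0.34), the forkhead factor FOXQ1 (5.21 ± 0.20), ATF3 (4.60 ± 0.17), CXCL8 (3.53 ± 0.25), VCAM1 (3.28 ± 0.25) and FOS (3.23 ± 0.21). These 3 DINO siRNA untreated arrays stood apart from the others: their highest 1% of deposited intensities began between 10468 and 11574, against 5264 to 8826 on the other 15 arrays. The second principal component on which they stood apart held 32.7% of the variance. On the first, which held 50.1%, the control siRNA untreated arrays stood apart. They lay at -71.7 and -74.4, against -5.66 to 34.1 on the other fibroblast arrays. INSM2, HAND1 and HOXD1, at background with the control siRNA, were at least 50.9-fold, 38.3-fold and 24.5-fold higher. Of the histone genes 19 were higher and 2 lower among 23 measured (20 and 2 adjusted over the list alone), with H2AC18 at 3.57, H2AC20 at 3.16 and H2BC8 at 2.98. Of the G2/M genes 4 were higher and 38 lower among 53 measured (4 and 38 adjusted over the list alone), with KIF11 at -3.63, CCNB1 at -3.32, CENPE at -3.12 and ECT2 at -2.97. For ribosome biogenesis, 3 were higher and 19 lower among 34 measured (3 and 19 adjusted over the list alone), with RRS1 at -2.84 and NAT10 at -2.34. For the p53 targets, 26 were higher and 13 lower among 70 measured (27 and 13 adjusted over the list alone), and the median was 0.26 (camera adjusted p = 0.043, adjusted p = 0.31 with an estimated correlation), with FUCA1 at 3.14, TNFRSF10A at 2.58 and GDF15 at 2.46. CDKN1A was at -0.65 ± 0.18 (adjusted p = 0.0075), against 0.03 in the deposited values without further normalization, 0.63 on its second probe and -0.01 with the mean of its probes, and MDM2 at -0.13 ± 0.19 (adjusted p = 0.60). ARID5B (-3.75), MRFAP1L1 (-3.58), KLHL9 (-3.52), the DNA sensor IFI16 (-3.49) and the adaptor TICAM1 (-3.43) were lower. Blood cell markers, a list for another cell type, were higher in 7 of 11 (8 adjusted over the list alone), with CD14 at 2.57 (camera adjusted p = 0.050, not called). Endothelial markers averaged a log2 intensity of 5.91 with the DINO siRNA and 5.55 with the control siRNA, and epithelial markers 5.66 and 5.62. The camera calls for histones (adjusted p = 3.5e-10), G2/M genes (6.5e-11) and ribosome biogenesis (1.3e-04) were lost (adjusted p = 0.31 each with an estimated correlation). The genes called here had adjusted p-values from 1.4e-14 to 0.0075.

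In the difference of responses, which uses the same untreated arrays, the values were as follows for FOSB (-6.58), FOXQ1 (-6.41), ATF3 (-4.38), IFI16 (3.74), ARID5B (3.72), KLHL9 (3.52) and PCDH18 (3.56). The histone genes H2BC8 (-3.57), H2AC18 (-3.50) and H2BC21 (-3.48) were lower, and in the list 1 was higher and 18 lower among 23 measured (1 and 19 adjusted over the list alone) (camera adjusted p = 1.8e-11, adjusted p = 0.27 with an estimated correlation). For G2/M genes, 32 were higher and 3 lower among 53 measured (33 and 3 adjusted over the list alone) (camera adjusted p = 7.7e-10, adjusted p = 0.35 with an estimated correlation). For ribosome biogenesis, 10 were higher and 1 lower among 34 measured (11 and 1 adjusted over the list alone), with RRS1 at 2.43 and NAT10 at 2.31 (camera adjusted p = 0.0013, adjusted p = 0.39 with an estimated correlation). Over all genes, 2532 were higher and 2296 lower in this difference, with adjusted p-values from 3.2e-12 to 0.029 for the genes named as changed.

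With doxorubicin, few genes differed between the siRNAs. The acute-phase inhibitor SERPINA3 was 2.61-fold higher with the DINO siRNA (log2 1.38 ± 0.24, n = 3 and 2, limma adjusted p = 0.030) and the methyltransferase INMT, at background with the control siRNA, was at least 2.05-fold higher. The matrix metalloprotease MMP3 (-1.78 ± 0.22, adjusted p = 0.0014), the histone gene H2BC21 (-1.36 ± 0.17, adjusted p = 0.0014), TAGLN3 (-1.42 ± 0.21), the mitotic kinase AURKA (-1.21 ± 0.21), FOXQ1 (-1.20 ± 0.20) and GLMP (-1.19 ± 0.19) were lower. CDKN1A was at 0.13 ± 0.18 (95% interval -0.26 to 0.51, adjusted p = 0.94) on its brightest probe, with -0.24 on its second, and MDM2 at -0.19 ± 0.19 (95% interval -0.58 to 0.20). By limma, 0 of 70 measured p53 targets passed the adjusted threshold and 7 had an unadjusted p under 0.05. FUCA1 was at 0.57 ± 0.17 and ACER2 at -0.63 ± 0.16, and for 67 of the 70 the 95% interval lay within a 2-fold difference.

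Over all genes, 2 were higher and 11 lower, and 1055 had an unadjusted p under 0.05. Fibroblast and matrix markers had a median of 0.19, with collagens COL1A1 (1.44 ± 0.31), COL3A1 (1.43 ± 0.33) and COL5A2 (1.35 ± 0.30) and the proteoglycan LUM (0.95 ± 0.21) not passing over all genes (5 of 33 higher adjusted over the list alone). The list's camera call (adjusted p = 1.7e-05) was lost with an estimated correlation (adjusted p = 0.42). Interferon-stimulated genes had a median of 0.16 (camera adjusted p = 0.0060, adjusted p = 0.19 with an estimated correlation). Without control siRNA doxorubicin replicate 2, which leaves 1 array in that group, limma called 0 higher and 0 lower genes (592 at an unadjusted p under 0.05), with MMP3 at -1.36 and SERPINA3 at 0.83. Without DINO siRNA doxorubicin replicate 2 it called 0 higher and 2 lower (993 at an unadjusted p under 0.05), and without replicate 3 it called 0 and 3 (845). Without control siRNA doxorubicin replicate 1 it called 3 and 5. Median scaling gave 7 higher and 14 lower, and the deposited values without further normalization 0 and 4.

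**Figure D3:**
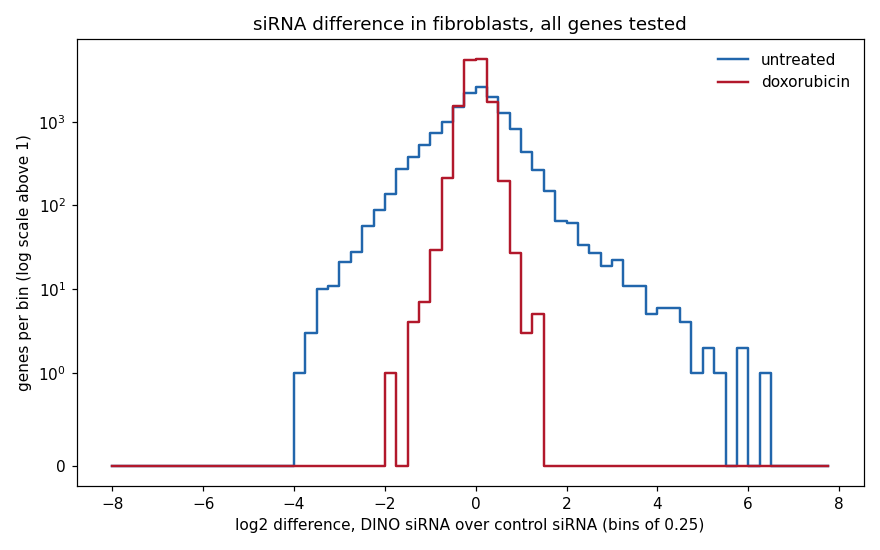
Number of genes per bin of the log2 difference between DINO siRNA and control siRNA fibroblasts, for untreated arrays (blue) and doxorubicin arrays (red), on a logarithmic count axis. The log2 differences had an SD of 0.83 untreated and 0.23 in doxorubicin, and 2677 and 20 genes differed at least 2-fold, called or not.

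The cell systems were linked through the genes called p53-dependent in HCT116, defined as changed in p53+/+ cells and changed more there than in p53-/- cells. The name stands for this difference by genotype, in which p53 cannot be told apart from other differences between the cells. This set held 691 genes that rose and 484 that fell. It held 349 and 203 without p53+/+ untreated replicate 1, 396 and 241 without replicate 2, 410 and 264 without p53+/+ doxorubicin replicate 1, and 321 falling genes without replicate 2. Without p53-/- doxorubicin replicate 1 it held 445 and 301, and without replicate 2 it held 425 and 257. Of the 648 rising genes measured in fibroblasts, 336 rose with the control siRNA (median log2 0.57) and 379 with the DINO siRNA (median 0.61), and of the 467 falling genes 222 (median -0.49) and 180 (median -0.20) fell. The median of the falling set was -0.76 with the control siRNA without p53+/+ untreated replicate 1, and -0.13 with the DINO siRNA without p53+/+ doxorubicin replicate 2. The rising set was called by camera in both responses (adjusted p = 4.9e-14 and 5.5e-15, and 0.0075 and 0.0063 with an estimated correlation). For the falling set the call with the control siRNA held (adjusted p = 2.2e-09, and 0.025 with an estimated correlation) and that with the DINO siRNA was lost (adjusted p = 6.0e-05, and 0.093 with an estimated correlation). Between the siRNAs in doxorubicin, the rising set had a median of 0.08 (camera adjusted p = 0.020, adjusted p = 0.34 with an estimated correlation) and the falling set -0.03 (adjusted p = 0.22). Across genes, which are not independent replicates, the DINO siRNA response of the 70 p53 targets was 0.598 times the control siRNA response (slope through the origin, jackknife SE 0.0385), and that of the 648 rising genes 0.506 times (SE 0.0610). The slopes weigh genes with large control siRNA responses most, and their jackknife SE is over arrays, not genes. Across genes the siRNA responses correlated at r = 0.67 for the p53 targets and 0.54 for the rising genes. The median ratio per gene was 0.705 for the p53 targets and 0.583 for the rising genes. The slopes and the ratios use the DINO siRNA untreated arrays, where the p53 targets had a median of 0.26 against the control siRNA. There the rising set had a median of 0.19 (camera adjusted p = 0.025, adjusted p = 0.23 with an estimated correlation).

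Of 13443 genes measured in both systems, 769 rose in p53+/+ HCT116 cells and in control siRNA fibroblasts, against 336 expected by chance (Fisher's exact test, p = 4.6e-148). In both, 684 fell, against 302 expected (Fisher's exact test, p = 1.5e-127). These p-values take genes as independent, which they are not, and do not measure the spread between arrays, of which each group had 2. The overlap of falling genes was 1076 with median scaling, and 363 falling and 483 rising genes overlapped without p53+/+ untreated replicate 1. The falling overlap was 404 without p53+/+ untreated replicate 2 and 428 without p53+/+ doxorubicin replicate 1. In the test of the difference, HCT116 minus fibroblasts, CBS (7.07 ± 0.25, n = 2 in each of 4 groups, limma adjusted p = 6.7e-17), thrombospondin THBS1 (4.36), TNFRSF19 (3.92), the receptor ADGRG1 (3.64), CCN1 (3.49), TP53I3 (2.92), SQLE (2.53), CDKN1A (2.48 ± 0.27) and MDM2 (1.77 ± 0.28, but -0.21 on its second probe) were higher. ULBP1 (-5.60), the lysosomal protease CTSV (-4.84), SNORD13 (-4.83), ATF3 (-3.83), DDIT3 (-3.34), FUCA1 (-3.17) and GDF15 (-3.00) were lower. Of the histone genes 1 was higher and 18 lower among 23 measured (1 and 19 adjusted over the list alone), with a median of -1.79 and with H2BC8 at -3.98 and H2AC20 at -3.71 (camera adjusted p = 1.3e-15, adjusted p = 0.052 with an estimated correlation). For the p53 targets, 24 were higher and 13 lower among 72 measured (27 and 15 adjusted over the list alone), with a median of 0.08 (camera adjusted p = 0.18). Of the CDKN1A neighbours, 3 of 9 were higher (3 adjusted over the list alone), with a median of 0.52 (camera adjusted p = 0.020, adjusted p = 0.13 with an estimated correlation). For endothelial markers, 1 was higher and 2 lower among 12 measured (1 and 2 adjusted over the list alone) (camera adjusted p = 0.56). Over all 16223 genes, 2011 were higher and 1952 lower (1469 and 2321 with median scaling), and the genes named had adjusted p-values from 6.7e-17 to 2.5e-05.

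In a few lists the median, the mean and the camera direction differed in sign, and camera called none of these lists. They were the CDKN1A neighbours in the p53+/+ response (-0.04, 0.16 and down) and in untreated HCT116 cells by genotype (-0.10, 0.21 and up), histones in the p53-/- response (-0.05, 0.07 and up) and cholesterol synthesis in the same response (0.02, -0.05 and down). In the p53-/- response the CDKN1A neighbours had a median of -0.03, a mean just above 0 and a camera direction of down. Between genotypes in untreated cells, the unfolded protein list (-0.03, 0.02 and down), the recombination list (median 0.01, mean -0.03, down) and epithelial markers (-0.03, 0.10 and up) differed so. In doxorubicin, epithelial markers (-0.10, 0.05 and up) and endothelial markers (0.10, -0.08 and down) did. In fibroblasts these were epithelial markers with the control siRNA (0.15, -0.01 and up), the NF-kB list with the DINO siRNA (0.03, -0.10 and down) and heat shock proteins in the siRNA difference in response (0.02, -0.03 and up), and between cell types epithelial markers (-0.04, 0.23 and up).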

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

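Of the tests in this part, those of sample treatment, of another dose or time, of short RNAs and of the DINO level were chosen after the result was seen, and those of an intensity-dependent stretch, of array number and of other splits before. For the stretch, the requirement that the lower quartile of the bins also pass was added after its values were seen. The results listed first were selected because 2 groups' responses differed by an interaction test. Of the lists below, those for p53 targets, p53 apoptosis targets, G2/M and homologous recombination between genotypes kept their call with an estimated correlation, and no list between siRNAs or cell systems did.

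The doxorubicin responses of the genotypes differed by the test of the difference itself, with 1115 genes higher and 936 lower in p53+/+ than in p53-/- cells. For the genotypes, the lists called by camera, with median log2 differences, were p53 targets (1.12), p53 apoptosis targets (0.75), p53 DNA repair targets (0.34), G2/M and mitosis (-1.33), G1/S and DNA replication (-0.59) and homologous recombination and Fanconi anemia (-0.94). The lists of the genotypes also included NF-kB and inflammatory secretion (-0.24), unfolded protein and ATF4 response (-0.24), immediate-early genes (-0.63) and blood cell markers (-0.39). Named genes higher in the difference between genotypes, with log2 values, were CBS (4.93), AKR1B10 (4.33), TP53I3 (4.23), TP53INP1 (3.87), SORCS2 (3.83), AKR1B15 (3.72), KLHL30 (3.13), PANK1 (2.91), ACTA2 (2.39) and RRM2B (2.18). Others higher between genotypes were MDM2 (2.12), PIDD1 (1.83), APAF1 (1.44) and XPC (1.34). Named genes lower in the difference between genotypes, with log2 values, were POLE2 (-1.72), UBE2T (-2.05), DLGAP5 (-2.11), NUF2 (-2.14), BRCA1 (-2.15), CENPE (-2.38), TTK (-2.50), FOS (-2.51), EGR1 (-2.54) and JUN (-2.60). Others lower between genotypes were UPP1 (-2.74), LBH (-2.88), MIX23 (-3.32), ANGPTL4 (-3.44), SLC2A3 (-3.53) and ANKRD37 (-3.99). CBS, SORCS2, AKR1B15, KLHL30 and LBH were at background in at least 1 group, so their values are no bounds, and a second MDM2 probe gave -0.48.

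The doxorubicin responses of the siRNAs differed by the test of the difference itself. In the DINO siRNA response 2532 genes were higher and 2296 lower than in the control siRNA response. This test subtracts the difference between the untreated arrays, where 3380 genes were higher and 3391 lower with the DINO siRNA. In doxorubicin 2 were higher and 11 lower, so the values below may rest on the untreated arrays. For the siRNAs, the lists called by camera, with median log2 differences, were G2/M and mitosis (0.96), homologous recombination and Fanconi anemia (0.71), histone genes (-1.70), ribosome biogenesis (0.42), fibroblast and matrix markers (0.32) and blood cell markers (-0.61). Named genes higher in the difference between siRNAs, with log2 values, were KIF11 (3.83), IFI16 (3.74), ARID5B (3.72), PCDH18 (3.56), CCNB1 (3.53), KLHL9 (3.52), ECT2 (3.21), CENPE (3.20), RRS1 (2.43) and NAT10 (2.31). Also higher between siRNAs was CDKN1A (0.78). Named genes lower in the difference between siRNAs, with log2 values, were ANKRA2 (-1.70), TNFRSF10A (-2.39), FUCA1 (-2.57), GDF15 (-2.97), H2BC21 (-3.48), H2AC18 (-3.50), H2BC8 (-3.57), ATF3 (-4.38), HOXD1 (-4.70) and ZCCHC12 (-4.78). Others lower between siRNAs were HAND1 (-5.46), INSM2 (-5.62), FOXQ1 (-6.41) and FOSB (-6.58). INSM2, HAND1, HOXD1 and ZCCHC12 were at background in untreated control siRNA cells, so their values are no bounds, and a second CDKN1A probe gave -0.87.

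The doxorubicin responses of the cell systems differed by the test of the difference itself, with 2011 genes higher and 1952 lower in p53+/+ HCT116 cells than in control siRNA fibroblasts. For the cell systems, the lists called by camera, with median log2 differences, were G2/M and mitosis (-0.27), histone genes (-1.79), unfolded protein and ATF4 response (-0.61), cholesterol synthesis (0.54), immediate-early genes (-0.19) and heat shock proteins (-0.32). The lists of the cell systems also included fibroblast and matrix markers (0.61) and CDKN1A neighbours (0.52). Named genes higher in the difference between cell systems, with log2 values, were CBS (7.07), THBS1 (4.36), TNFRSF19 (3.92), ADGRG1 (3.64), RGS4 (3.56), SORCS2 (3.50), CCN1 (3.49), KLHL30 (3.25), TP53I3 (2.92) and SQLE (2.53). Others higher between cell systems were CDKN1A (2.48) and MDM2 (1.77). Named genes lower in the difference between cell systems, with log2 values, were GDF15 (-3.00), FUCA1 (-3.17), DDIT3 (-3.34), H2AC20 (-3.71), ATF3 (-3.83), H2BC8 (-3.98), H2AC8 (-4.20), SNORD13 (-4.83), CTSV (-4.84) and SHISA2 (-4.86). Others lower between cell systems were CRTAC1 (-5.03), ULBP1 (-5.60) and GRAP (-5.73). RGS4, SORCS2, KLHL30, H2AC8, SHISA2, CRTAC1 and GRAP were at background in at least 1 group, so their values are no bounds, and a second MDM2 probe gave -0.21.

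Untreated DINO siRNA arrays differed from untreated control siRNA arrays at 3380 higher and 3391 lower genes. These differences correlated across genes with the doxorubicin response of control siRNA cells (r = 0.74, against 0.547 in simulations with replicate noise alone). A shift of the control siRNA untreated arrays as a group would enter both sides and was not simulated, so this correlation cannot show a likeness beyond shared arrays. Arrays treated like the doxorubicin arrays are argued against, since the p53 targets still rose by a median log2 value of 0.91 with doxorubicin in DINO siRNA cells. An intensity-dependent stretch as the whole cause is argued against too, since it would move genes of equal brightness together. Within brightness bins the SD of log2 differences was a median of 3.83 times that in doxorubicin (quartiles 2.65 and 4.33). These values were quantile-normalized, so they cannot tell whether the deposited values held a stretch. As the whole cause, another yield of short RNAs is also argued against. Outside small RNAs and histones, 2627 genes were called at 2-fold or more. Another dose or time of doxorubicin stays open, with the p53 targets at a median of 0.26 (adjusted p = 0.31 with an estimated correlation), and an effect of the DINO siRNA itself on untreated cells may also account for it and was not tested apart. A separate handling of the DINO siRNA untreated arrays stays open too. It cannot be told apart from the siRNA, since the labels give no batch and all 3 arrays stand apart. Their highest 1% of intensities began at 10468 to 11574 (at most 8826 on the others). On them 604 to 1106 values were below 0, more than on any of the other 15 arrays. Their second principal component was -51.7 to -41.7 (14.6 to 24.4 on the other fibroblast arrays). On the first component the control siRNA untreated arrays stood apart, at -71.7 and -74.4 against -5.66 to 34.1. These values therefore do not place the difference on the DINO siRNA arrays alone.

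Few genes differed between the siRNAs in doxorubicin. Of simulated 2-fold differences 95% were called, but this cannot decide whether too few arrays were used. The simulation held 100 2-fold and 100 4-fold changes, and many changed genes make the adjusted threshold easier to pass. Here 20 genes differed at least 2-fold, and 2 higher and 9 lower genes were called at that size. The 95% intervals of 97.8% of the 14814 genes lay within 2-fold, which argues against larger differences for those of them well above background. For dim genes it does not, since the offset draws their differences toward 0. Between untreated siRNAs the SD of log2 differences was 0.35 in the dimmest of 20 brightness bins and 1.07 in bin 10. The share was not computed for genes above background alone. Whether DINO was lowered by its siRNA could not be told, as 0 of the probes used carried its name, and an siRNA that left DINO unchanged may account for the pattern as may a small role of DINO at 26 hours.

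In the DINO siRNA doxorubicin response, the real split of the 6 arrays called 6356 genes and the highest of the other splits 0 by limma at the adjusted threshold, and 1 of the 10 splits, the real one, gave as many, which are too few splits for a share under 0.05.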

How the results depend on the processing

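The fit without the DINO siRNA untreated arrays was chosen after the data were seen, and all other alternatives before. Of 5377 values of named genes under alternatives, 5290 kept their direction and side of the threshold, 57 lost a call, 24 gained one and 6 reversed, counting a value called under neither setting as kept. Of 4085 list values, 3838 kept both, 170 lost a call, 76 gained one and 1 reversed, and of 715 counts and other results 618 were kept. The list total pools unlike settings. With an estimated correlation alone, 70 of 209 list results lost their call and 139 were kept, which includes lists called under neither setting. The slide could not be used as a block, since no slide is given. Array signal over background limits what can be measured of dim genes. Except where stated, the cause of the changes below was not tested.

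With median scaling, the lower genes numbered 2584 in the p53+/+ response, 1432 in the genotype difference in response and 718 between untreated genotypes, the lower genes of the p53-dependent set 885 and the lower overlap 1076. The slopes were 0.662 for p53 targets and 0.568 for the rising p53-dependent set with median scaling, and 0.557 for p53 targets with the deposited values. With only the arrays compared, untreated genotypes differed at 811 higher and 683 lower genes. Requiring at least a 2-fold change, which narrows the set by construction, left 350 rising and 200 falling p53-dependent genes and overlaps of 213 and 159. WNT16 between untreated genotypes went to 0.16 over all 18 arrays, and HAS2 in the control siRNA response to 0.23 over all 18 arrays, 0.23 without background correction and 0.20 in the deposited values, since another probe became the brightest. CDKN1A went to -0.0483 in the siRNA difference in response with the mean of all probes, and to 0.0284 between untreated siRNAs in the deposited values, where the matrix list median in the siRNA difference in response was -0.0650.

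Between siRNAs in doxorubicin (2 higher and 11 lower), the counts were 14 and 25 over all 18 arrays, 13 and 33 with array weights, 10 and 25 with an intensity trend, 5 and 18 with an offset of 50, and 1 and 3 with a replicate block. Without background correction and in the deposited values limma called 0 higher and 4 lower (1039 and 987 genes at an unadjusted p under 0.05), with the mean of all probes 1 higher and with median scaling 7 higher. The rising p53-dependent set there had medians of 0.0678 without a filter (adjusted p = 0.081), 0.0537 with array weights (0.050), 0.0494 with a replicate block (0.12) and 0.0760 with an estimated correlation (0.34), none past the threshold. The falling set passed it at -0.0564 with median scaling (adjusted p = 0.027), -0.0406 in the deposited values (0.048) and -0.0437 with the 2-fold set (0.050), and in the DINO siRNA response it stayed at -0.20 but lost its call with an estimated correlation (adjusted p = 0.093).

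Leaving out each array in turn, which leaves fewer samples, gave these ranges for counts. The range for the p53+/+ response was 938 to 1261 higher and 701 to 1022 lower, and for the p53-/- response 741 to 1851 higher and 789 to 1943 lower. Counts ran for the genotype difference in response from 580 to 1679 higher and 423 to 1601 lower, and for untreated genotypes 443 to 1797 higher and 305 to 1745 lower. The range for genotypes in doxorubicin was 1407 to 1560 higher and 1039 to 1245 lower, and for siRNAs in doxorubicin 0 to 3 higher and 0 to 11 lower. Counts ran for the p53-dependent set from 349 to 916 higher and 203 to 710 lower, and for the overlap of the cell systems 483 to 684 higher and 363 to 587 lower. Median log2 values of the p53-dependent sets between siRNAs in doxorubicin ran from 0.0345 to 0.101 (rising) and from -0.0504 to -0.00481 (falling).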

Other observations

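The list of hypoxia-associated genes was written after the p53-/- response had been seen, and its predictions were set before its result was seen. The requirement of an estimated-correlation p for the test of both genotypes was added after its value was seen.

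Genes known to respond to low oxygen were tested as a list in HCT116 cells, because ANKRD37, ANGPTL4, SLC2A3 and BHLHE40 led the p53-/- response, with genes named elsewhere in the text left out of the list. Of 53 measured genes, 27 rose and 1 fell in the p53-/- response, with a median of 0.59 (camera p = 8.0e-12, and p = 0.035 with an estimated correlation). In the p53+/+ response 13 rose and 4 fell, with a median of 0.14 (camera p = 0.016, and p = 0.33 with an estimated correlation). A low-oxygen type response of the p53-/- cells is a candidate explanation that met its prediction. The list was prompted by leading genes of the same response and tested on the same arrays, so this is no independent support. Whether both genotypes share it stays open, since the genotype difference had a median of -0.43, below the bound set for excluding it, but its p with an estimated correlation was 0.14 (camera p = 5.0e-05), which does not lie beyond the spread of the list.

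Across genes, the difference between untreated siRNAs correlated with the control siRNA doxorubicin response at r = 0.74. Both use the control siRNA untreated arrays. With replicate noise alone, 20 simulations gave a mean r of 0.547, with a covariance of 0.0229 against 0.513 measured. The simulations held no shift of the control siRNA untreated arrays as a group, which would enter both comparisons. They therefore cannot show a likeness beyond the shared arrays. In both comparisons, 1881 genes were higher and 2029 lower, and 168 went in opposite directions.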
